A study of Mus musculus with 4 samples.

How the data were processed

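RNA from 4 cultures of NF639, a mouse mammary tumour cell line derived from a tumour driven by the ErbB2 (Her-2/neu) oncogene, was hybridised to Affymetrix Mouse 430A 2.0 arrays, 1 array per culture. The labels place 2 arrays in the original population and 2 in a pool of cells resistant to epigallocatechin gallate (EGCG), the main polyphenol of green tea. Per the labels, the RNA came from separate experiments. The labels do not say that the number of a replicate marks an experiment, nor whether EGCG was present at harvest.

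The deposited values are MAS5 signal intensities on a linear scale, 1 value per probe set and array, as the submitters' processing notes name MAS5. MAS5 summarises the perfect-match and mismatch probes of a probe set into 1 background-adjusted intensity, so that dim probe sets carry large relative errors. The software version is not given in the sources used here, and detection calls were not used here. In the deposited intensities the mean without the top and bottom 2% of probe sets was 500.2 on each of the 4 arrays, so a global difference in RNA content between the populations would have been scaled away by the authors. Signals ran from 0.1 to 25919.2. The median signal per array was 135.2 and 115.2 in the original population and 128.6 and 114 in the resistant pool. For arrays there is no count behind a value, and the number of arrays limits the precision.

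The table held 22690 probe sets, of which 64 were array controls that took no part in the tests. Gene names came from the platform annotation paired with the probe sets. It gave 1 symbol for 20380 probe sets, several for 691 and listed none of the remaining 1555, which are unnamed here. Of the probe sets with 1 symbol, 20351 matched the GRCm38.p6 gene table by gene identifier, and 0 symbols needed an update. That assembly served only for names and for the order of neighbouring genes, and no coordinates are given because the values carry no genome build. A probe set with several symbols named no gene.

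The arrays were scaled to a common 2% trimmed mean over the probe sets that are not controls, which changed the deposited values very little, and log2(signal + 3) was taken. The pseudocount of 3 is the rounded 10th percentile of all signals. Fold changes are on this scale, which understates the change of dim genes. Probe sets whose mean over the 4 arrays lay under the 40th percentile, a signal of 49.1, were left out, and 13576 probe sets were tested. limma 3.58.1 in R 4.3.3 fitted resistant minus original (lmFit, then eBayes with a mean-variance trend), and two-sided p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A gene took the values of its retained probe set with the highest mean, which gave 7510 genes; its adjusted p comes from the fit over all retained probe sets.

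Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists, and again with an estimated correlation. At the preset correlation camera's p-values rest on the spread between genes and not between cultures. With an estimated correlation they rest on the few residual degrees of freedom of 4 arrays. The fry method gave directional and mixed tests. The 33 lists cover signalling, cell identity, stress, metabolism and the cell cycle. They were fixed before the data were examined, as were the groups, the fit, the rule for naming genes and the first set of alternatives. The rule named up to 12 genes with the largest rise and up to 12 with the largest fall among those past the threshold whose arrays did not overlap between the groups, up to 4 called members of each list, and 17 genes of the ErbB, MAPK and cell identity pathways whatever their test. Genes named outside that rule were chosen after their values were seen; these are the list members that passed only when adjusted over the list alone or when the hybridisation batch was a term, the genes at the ends of chromosome runs, and some genes of the additional observations.

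The spiked hybridisation controls BioB, BioC and BioDn, which are added to the hybridisation mix, were compared between arrays to look for batches. Because BioB, BioC and BioDn split the arrays by replicate number in both groups, values are also given with the replicate number as a block in the limma fit and within each number. That fit leaves 1 residual degree of freedom, and limma then estimated infinite prior degrees of freedom, so its p-values rest on 1 spread shared by probe sets of like brightness. In the fit without the block the prior degrees of freedom were 8.3.

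The procedure was tested on simulated data, with 200 of the 13576 probe sets changed in each of 10 simulations. It recovered 37.61% of those changed 2-fold, 91.04% of those changed 4-fold and 98.94% of those changed 8-fold, and 4.82% of the calls were false. The simulated spread was drawn from limma's own estimate, so these shares hold only where that estimate is right. In the real arrays only 23 probe sets passed, which makes the adjusted threshold stricter, so recovery there may be lower. A list whose members were all shifted alike was called in 10 of 10 simulations. Simulated probe sets varied independently of each other, so this does not show how camera behaves when the genes of a list are correlated. When arrays of the same number also shared a simulated shift, the fit without the block recovered 24.2% of the 2-fold changes with 0.358% false calls. The fit with the block then recovered 63.4% of them with 12.5% false calls, above the nominal share, and its prior degrees of freedom were finite in all 10 simulations, unlike those of the real arrays.

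Alternatives changed the pseudocount, the scaling, the filter, the variance model, the block, the probe set that stands for a gene and the inter-gene correlation, and left out each array in turn. A pseudocount of 64, alone and with the block, was added after the data were seen. Neighbouring genes were compared in windows of 25 measured genes along the gene order of GRCm38.p6, against 1000 shuffled orders.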

Results

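Gene expression was measured in NF639 mouse mammary tumour cells of the original population and of a pool resistant to EGCG, with 2 arrays in each group. The comparison asks which transcripts differ in abundance between the resistant cells and the original population. Over the tested probe sets the log2 signals of the arrays correlated at 0.9754 within the original population and 0.9728 within the resistant pool. Arrays of different groups with the same replicate number correlated at 0.9729 and 0.9715, and those with different numbers at 0.9651 and 0.9631. These are correlations across probe sets, which are not independent replicates.

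By their spiked BioB, BioC and BioDn controls the arrays fell into 2 sets that follow the replicate number. These sets are called hybridisation batches here, though no label names a batch. Each of the 7 probe sets for the spiked BioB, BioC and BioDn controls was brighter on the array numbered 2 of its group, by 1.39 to 2.11 times in the original population and by 1.48 to 2.29 times in the resistant pool. Between arrays of the same number the ratio of resistant over original was 0.938 to 1.01 in the first batch and 0.991 to 1.14 in the second. The probe sets of the brightest spiked control, Cre, did not all split in this way: CreX-3 had signals of 7895.8 and 7859.7 on the original arrays and 7569.8 and 8407.4 on the resistant ones, and CreX-5 6020.8 and 5968, and 5916.6 and 6421.2. The array of the second original culture also stood apart in its poly-A spike controls, with a median signal of 219.65 against 119.15, 110.95 and 120.75, and in the 18S ribosomal RNA probe set, with 4005.3 against 362.4, 346.7 and 624.3. The ratio of 3′ to 5′ signal of Actb overlapped between the groups, at 1.17 and 1.16 in the original and 1.24 and 1.13 in the resistant arrays. That of Gapdh did not overlap, at 0.754 and 0.772 in the original and 0.788 and 0.798 in the resistant arrays. Each of these inferred batches held 1 array of each group, so the batch could be made a term of the fit. Results with that term rest on the inference from the spiked controls. Values within each batch are given for some genes and lists.

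**Figure D1:**
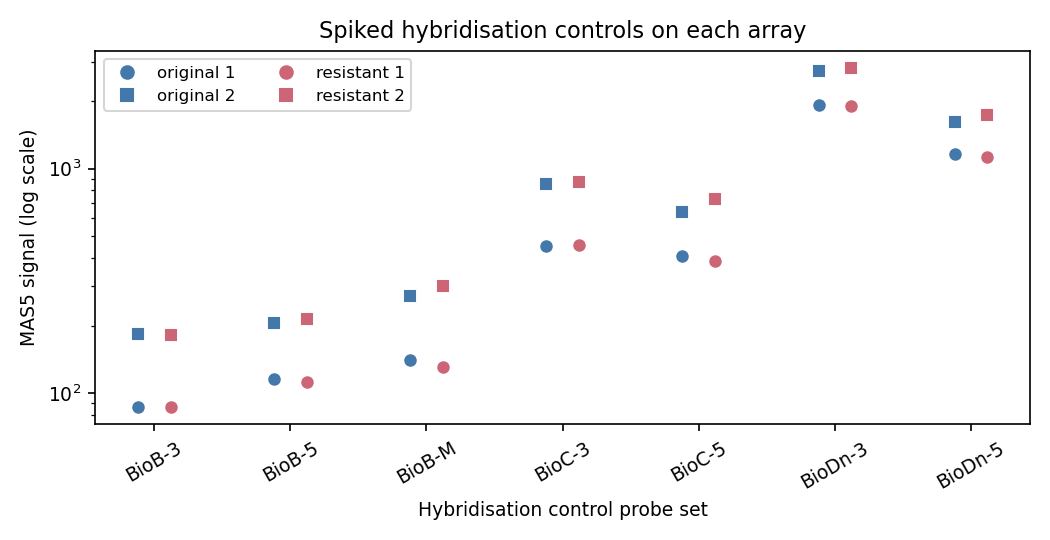
MAS5 signal (log axis) of the 7 probe sets for the spiked BioB, BioC and BioDn controls on each of the 4 arrays, in blue for the original population and red for the resistant pool, with circles for replicate 1 and squares for replicate 2. In each of these 7 the squares lie above the circles, by 1.39 to 2.29 times, and arrays with the same number lie close together.

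In the resistant pool the actin-binding genes Tagln (transgelin, a marker of smooth muscle and myofibroblasts), Tmsb4x (thymosin beta, which binds actin monomers) and Cotl1 (which binds actin filaments) rose. Tagln went from a signal of 8.35 ± 5.16 (SD, n = 2) in the original population to 450.4 ± 461 (SD, n = 2), a log2 fold change of 4.87 ± 0.732 (SE). Its size differed between the batches, at 3.09 in the first and 6.66 in the second, and its original signals lay near the floor of the scale. The call ended at larger pseudocounts, with a log2 fold change of 3.74 at the 25th percentile of signals and 2.46 at 64, which was chosen after the data were seen. Tmsb4x rose by 2.22 ± 0.353 (SE) and Cotl1 by 1.49 ± 0.206 (SE) on the log2 scale. The size for Tmsb4x also differed between the batches, at 1.30 in the first and 3.14 in the second, and was 1.59 without resistant 2. All 5 retained probe sets of Cotl1 were higher in the resistant pool, and 1 of them passed on its own.

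Vcan, Atp1b1, Lamb3 and Col5a3 fell. Vcan, which encodes the matrix proteoglycan versican, fell by 4.38 ± 0.534 (SE) on the log2 scale, from 364 ± 133 to 16.8 ± 14.3 (SD, n = 2 per group). With a pseudocount of 64 its log2 fold change was -2.38, since its resistant signals lay near the floor. With the pseudocount of 3 it was -3.19 in the first batch and -5.57 in the second. Atp1b1, the beta subunit of the sodium-potassium ATPase, fell by 3.72 ± 0.247 (SE), from 2239 ± 560 to 167 ± 42.0 (SD, n = 2 per group), and all 4 of its probe sets passed. It had the smallest adjusted p of all genes (limma, Benjamini-Hochberg adjusted p = 0.000322). Lamb3, a chain of the epithelial basement membrane laminin, fell by 1.24 ± 0.196 (SE), and Col5a3, a type V collagen chain, fell by 1.05 ± 0.167 (SE).

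The chemokines Ccl2 and Ccl7, neighbours in the gene cluster of monocyte attractants, both fell. Ccl2 went from 4618 ± 408 to 1754 ± 221 and Ccl7 from 777.2 ± 188 to 247 ± 7.85 (SD, n = 2 per group), falls of 1.40 ± 0.172 (SE) and 1.62 ± 0.233 (SE) on the log2 scale. Rhox5, a homeobox gene of the X-linked reproductive cluster, fell by 2.79 ± 0.223 (SE), from 3524 ± 76.6 to 520.8 ± 172 (SD, n = 2 per group). Blnk, an adaptor of B-cell receptor signalling, fell by 3.39 ± 0.515 (SE; -2.26 and -4.52 in the batches), Tmem185b fell by 2.66 ± 0.365 (SE) and the lipoprotein receptor gene Vldlr fell by 2.23 ± 0.325 (SE). With a pseudocount of 64 the log2 fold changes of Blnk, Tmem185b and Vldlr were -1.80, -1.56 and -1.54. Blnk and Tmem185b were dim: their resistant signals (27.8 and 12.1, and 40.1 and 26) lay under the filter's signal of 49.1. Of the other risers, Ms4a4d, a member of the membrane-spanning 4A family, went from 112 ± 14.8 to 982.6 ± 326 (SD, n = 2 per group), a log2 rise of 3.06 ± 0.275 (SE). Mgll, the lipase that cleaves monoacylglycerols, rose by 2.38 ± 0.342 (SE; 1.54 with a pseudocount of 64, with original signals of 61.8 and 38.6), Tcl1b3 by 2.21 ± 0.318 (SE; 1.44 and 2.98 in the batches) and the G-protein subunit gene Gng11 by 1.60 ± 0.242 (SE). The probe sets of Mgll, Tcl1b3, Cotl1 and Vldlr are of the kinds that the array design marks as able to bind related transcripts. Atp1b1 and Blnk lie in runs of neighbouring genes that were lower together, with medians of -0.309 and -0.329 over 25 genes. These medians are far smaller than the falls of Atp1b1 and Blnk themselves.

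**Figure D2:**
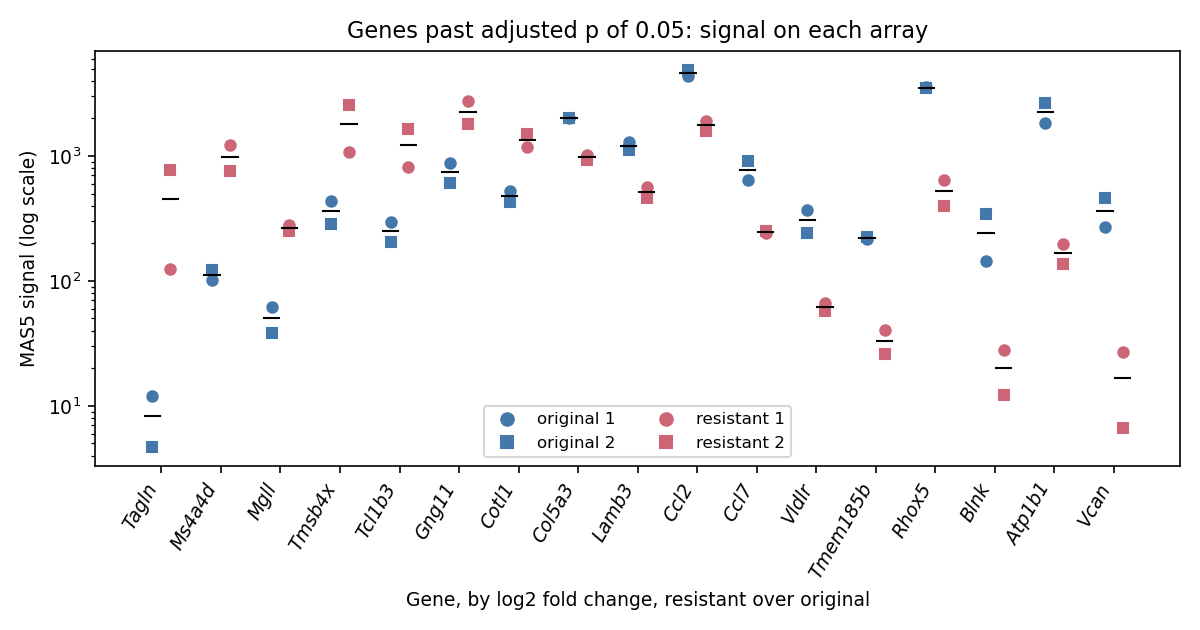
MAS5 signal (log axis) of the 17 genes past an adjusted p of 0.05 on each of the 4 arrays, in blue for the original population and red for the resistant pool, circles for replicate 1 and squares for replicate 2, with a bar at the mean of each group (n = 2). Genes are ordered by fitted log2 fold change, from Tagln (4.87) to Vcan (-4.38). The order depends on the pseudocount: at 64 Ms4a4d (2.54) exceeds Tagln (2.46), and Atp1b1 (-3.31) and Rhox5 (-2.65) fall by more than Vcan (-2.38). In each gene both resistant arrays lie on the same side of both original arrays.

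With limma and Benjamini-Hochberg adjustment, 23 of 13576 probe sets passed, 8 higher and 15 lower in the resistant pool, and all 23 differed at least 2-fold. They represent 17 genes, 7 higher and 10 lower, with adjusted p between 0.000322 for Atp1b1 and 0.0487 for Tmsb4x and Col5a3. Among the other called probe sets, 2 are not named here (log2 fold changes -2.77 and -2.25), and Dipk2a had 1 called probe set (1.27, adjusted p = 0.0376) whose brighter partner did not pass. At an unadjusted p under 0.05 there were 998 probe sets, 466 higher and 532 lower. The groups did not overlap in 36% of probe sets; chance gives 33.3% for 4 exchangeable arrays, which arrays that share a batch are not. With the hybridisation batch as a block, 710 probe sets passed (303 higher, 407 lower), which include all 23, and 433 genes (203 higher, 230 lower), which include all 17. Every one of the 17 had the same sign in both batches, which follows from their arrays not overlapping between the groups. Atp1b1, Ms4a4d and Rhox5 passed in every alternative that measured them except limma without a variance trend. The number of genes called depended on the variance model and the filter: limma without a variance trend called 0 genes (922 probe sets at an unadjusted p under 0.05), quantile normalisation 4, no filter on dim probe sets 3 and a filter at the 60th percentile 7, while leaving out 1 array gave 97 (without original 1), 48 (original 2), 53 (resistant 1) and 69 (resistant 2).

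Genes that NF-kappaB is known to induce were lower as a group in the resistant pool. Their median log2 fold change was -0.64 over 19 measured members (SD 0.529 between genes), with 14 fitted below 0. Ccl2 was the 1 member that passed over all genes tested, and 8 passed, all lower, when adjusted over the list alone. With the batch as a term 10 passed, all lower. These were the chemokines Ccl2, Cxcl1 (-0.80) and Cxcl5 (-1.05), the adhesion molecule Vcam1 (-1.41), the growth factor Csf1 (-0.64), and Traf1 (-1.03), Nfkb2 (-0.97), Nfkbia (-0.46), Nfkbie (-0.96) and Tnfaip3 (-0.91), which encode components and feedback inhibitors of the pathway itself. The list's median was -0.57 in each batch and -0.37 without original 1. The camera test passed (adjusted p = 3.38e-07, and 2.12e-11 with the batch as a term), and adjusted p = 0.643 with an estimated correlation. Markers of leukocytes and endothelium had a median of -0.17 over 5 measured members and did not pass (camera adjusted p = 0.723).

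Mesenchymal markers were higher as a group, with a median log2 fold change of 0.48 over 20 measured members (SD 1.2) and 15 fitted above 0. Tagln was the 1 member that passed over all genes tested, and 5 passed higher and 1 lower when adjusted over the list alone. With the batch as a term 7 passed higher: Tagln, the smooth muscle actin gene Acta2 (1.79), the matrix genes Postn (1.88), Col3a1 (1.99), Col1a1 (0.99) and Col6a1 (0.82), and the fibronectin gene Fn1 (0.42; 0.03 and 0.80 in the batches). Col1a2 was the 1 member lower in that fit (-0.62). Acta2 differed between the batches, at 0.32 in the first and 3.26 in the second. The camera test passed (adjusted p = 5.06e-05, and 1.73e-09 with the batch as a term), and adjusted p = 0.643 with an estimated correlation; the median was 0.34 and 0.50 in the batches. The call ended with a filter at the 60th percentile (median 0.16), and without original 2 the median was 0.22. Vim, the mesenchymal intermediate filament gene, had signals of 18620 ± 843 and 17910 ± 2870 (SD, n = 2 per group) and did not pass (limma adjusted p = 0.991). Fibroblast markers, of which 5 measured members are also in the mesenchymal list, had a median of 0.50 over 11 measured members with members on both sides, among them Dcn at -2.15 ± 0.699 (SE) and Col3a1 at 1.99. They did not pass (camera adjusted p = 0.0723, and 0.00196 with the batch as a term). Basal and myoepithelial markers, of which 3 are also in the mesenchymal list, held Tagln among the risers and Vcan among the fallers and did not pass as a group (median 0.09 over 7, adjusted p = 0.723).

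Genes of hypoxia and glycolysis were lower, with a median of -0.43 over 19 measured members and 17 fitted below 0. None passed over all genes tested, 5 passed lower when adjusted over the list alone, and 10 passed lower with the batch as a term. Among these were Pdk1 (-1.65; -0.86 and -2.45 in the batches), which restrains pyruvate oxidation, Bnip3 (-1.59; -0.93 and -2.25 in the batches), a hypoxia-induced mitophagy receptor, the histone demethylase gene Kdm3a (-0.84) and the glucose transporter gene Slc2a1 (-0.60). The camera test passed (adjusted p = 7.36e-07, and 2.12e-11 with the batch as a term), and adjusted p = 0.718 with an estimated correlation. The inter-gene correlation of this list was estimated at 0.528, far above the preset value. If that estimate holds, the p-values at the preset correlation are much too small, though the estimate itself rests on few residual degrees of freedom. The list also differed within the original population, by a median of 0.47 for array 2 minus array 1, and by 0.25 within the resistant pool. The difference within the original population exceeded the size of that between the groups (-0.43), so variation between cultures stays open for this list. The medians within the batches were -0.30 and -0.50. The size rested on single arrays: the median was -0.09 without original 2, -0.24 without resistant 1 and -0.73 without original 1, and the camera call held in each.

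Endoplasmic reticulum chaperones and other genes of the unfolded protein response were lower, with a median of -0.29 over 24 measured members and 19 fitted below 0. None passed over all genes tested or adjusted over the list alone, and 10 passed lower with the batch as a term, among them the transcription factor gene Xbp1 (-0.57), the chaperone genes Hspa5 (-0.35) and Calr (-0.41) and the disulfide isomerase gene Pdia4 (-0.85). Camera gave an adjusted p = 3.72e-06 (6.05e-07 with the batch as a term), and adjusted p = 0.643 with an estimated correlation. Genes of the integrated stress response and amino acid synthesis had a median of -0.18 over 24 members. Vldlr passed over all genes tested, 3 passed lower when adjusted over the list alone, and with the batch as a term Vldlr, Cth (-2.09), which makes cysteine from cystathionine, and Phgdh (-1.04), the first enzyme of serine synthesis, were lower and Ddit4 (0.54) was higher, though only in the first batch (1.12, against -0.04 in the second). Camera gave an adjusted p = 0.00331 (0.00274 with the batch as a term), and adjusted p = 0.718 with an estimated correlation. The call also ended with a filter at the 60th percentile (median -0.03), without original 2 (-0.01) and without resistant 1 (-0.27), and the median was -0.37 without original 1 and -0.38 without resistant 2.

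The cell-cycle lists had medians of opposite sign, a difference that was not itself tested. Genes of G2 and mitosis had a median of -0.23 over 29 measured members, 23 of them fitted below 0 (-0.15 without resistant 2). None passed over all genes tested, and 4 passed lower both when adjusted over the list alone and with the batch as a term: the kinetochore genes Cenpe (-0.85) and Cenpf (-0.72), the spindle motor gene Kif23 (-0.67) and Ube2c (-0.64), a ubiquitin-conjugating enzyme of mitotic exit. Genes of DNA replication had a median of 0.16 over 32 measured members, 28 of them fitted above 0. None passed over all genes tested or over the list alone, and Ccne1 (0.91), a cyclin of S-phase entry, and Rfc3 (0.64) passed higher with the batch as a term. Camera passed for both lists, with adjusted p = 4.12e-06 for G2 and mitosis (1.18e-05 with the batch as a term) and 0.00154 for replication (0.00341 with the batch as a term). With an estimated correlation they had adjusted p = 0.643 and adjusted p = 0.718. Antigen presentation genes were lower (median -0.31 over 12 measured members, camera adjusted p = 0.018, and 0.0398 with the batch as a term), and adjusted p = 0.828 with an estimated correlation. That correlation was 0.39, also far above the preset value, so the same limit holds for this list. Tapbp (-0.63) and the immunoproteasome subunit gene Psmb8 (-0.89) passed lower and B2m (0.38) higher with the batch as a term; over all genes tested 0 passed, and 2 passed lower when adjusted over the list alone. The call of the list also ended without the filter on dim probe sets (median -0.23), without original 1 (-0.13) and without resistant 1 (-0.25).

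**Figure D3:**
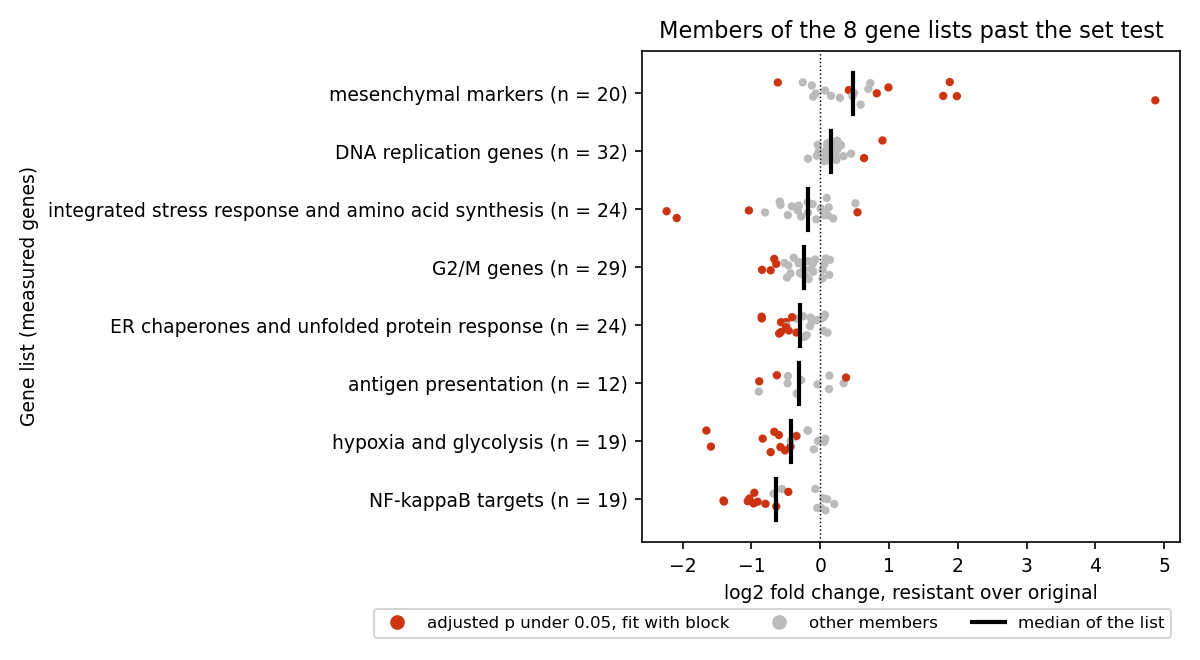
Log2 fold change, resistant over original, of each measured member of the 8 gene lists past the camera test at a preset correlation, with the list's median as a bar and members past an adjusted p of 0.05 with the hybridisation batch as a block in red. The medians run from -0.64 for NF-kappaB targets to 0.48 for mesenchymal markers, and every list has members on both sides of 0.

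Of the 33 lists, 8 passed the camera test at the preset correlation, 2 higher and 6 lower, all 8 also passed with the batch as a term, and 0 passed with an estimated correlation. Among these 8 the estimates ran from 0.00151 for the unfolded protein response to 0.528 for hypoxia and glycolysis. Only the former lay below the preset value. In fry, which sets no list against other genes, 0 lists passed the directional test, and the mixed test passed for G2 and mitosis (adjusted p = 0.0352) and for the integrated stress response (adjusted p = 0.0317).

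Genes of the pathways through which ErbB receptors signal showed no called change in the test over all genes. Erbb2, the mouse gene of the receptor whose oncogenic form drove the tumour, had signals of 309.5 ± 14.4 and 303.4 ± 32.2 (SD, n = 2 per group), a log2 fold change of -0.03 ± 0.232 (SE, limma adjusted p = 0.998); whether its probes also read the oncogene's transcript was not tested. Egfr stood at -0.06 ± 0.312 (SE). The MAP kinase kinases Map2k1 (-0.44, 95% confidence interval -0.82 to -0.05, adjusted p = 0.602) and Map2k2 (0.26, adjusted p = 0.843) did not pass, nor did Gsk3b (0.20), Ccnd1 (-0.21), Cdkn1b (0.16), Zfp36 (0.14) or Myc (-0.32). Foxo3 had 2 probe sets of opposite sign (0.49 and -0.13), neither past the threshold. Erbb3, Esr1, Fos and Cdh1 lay under the filter on dim probe sets. As a list, the MAP kinases with RAS and RAF had a median of 0.11 over 29 measured members (camera adjusted p = 0.526), targets and feedback regulators of ERK a median of -0.12 over 16 (adjusted p = 0.746), ErbB receptors and ligands -0.06 over 5 (adjusted p = 0.723) and the PI3K, AKT and FOXO pathway 0.05 over 25 (adjusted p = 0.723). The ERK target Egr1, an immediate early transcription factor, had a log2 fold change of 1.12 ± 0.190 (SE), missed the threshold over all genes tested (limma adjusted p = 0.0582) and passed when adjusted over the list alone and with the batch as a term. With that term the ERK targets Fosl1 (-0.76), Plaur (-0.75) and Emp1 (-0.44) and the ErbB ligand gene Hbegf (-0.53) passed lower and the MAP kinase gene Mapk12 (0.93) higher. Hbegf was lower only in the first batch (-1.20, against 0.14 in the second).

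Genes that handle polyphenols and oxidants, and the laminin system through which EGCG is known to bind cells, were weighed in the same way. NRF2 targets and antioxidant enzymes had a median of -0.03 over 28 measured members (camera adjusted p = 0.897). Enzymes and transporters of polyphenol conjugation and efflux had a median of -0.16 over 11 (adjusted p = 0.119), with Cyp1b1 (-1.09) and Slco2a1 (-0.79) lower when adjusted over the list alone. The laminin receptor, laminins and integrins had a median of -0.13 over 14 (adjusted p = 0.0907), with Lamb3 the 1 called member; with the batch as a term Lamb1 (-0.55) was also lower and Itga5 (0.52) higher, the latter only in the second batch (1.12, against -0.08 in the first). Lysosome and autophagy genes had a median of 0.10 over 28 and did not pass (adjusted p = 0.0723, and 0.0326 with the batch as a term), and epithelial markers had only 4 measured members (median 0.06, adjusted p = 0.766). The other lists that did not pass had adjusted p between 0.32 and 0.971.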

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

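All 17 called genes kept their direction in every alternative that measured them, and so did all 8 called lists. The arrays of these genes did not overlap between the groups. Leaving out an array or changing the pseudocount, the variance model or the block could therefore not turn their sign. How many genes and lists passed depended on the setting. Pseudocounts, the values as deposited, median centring, robust eBayes and the mean of a gene's probe sets kept the totals within 1.5 times, though 16 genes were lower, against 10, at a pseudocount of 64 and with the mean of a gene's probe sets, and single calls ended: Tmsb4x and Col5a3 under median centring, Tagln, Tmsb4x and Tcl1b3 under robust eBayes, and Cotl1 and Mgll as means of their probe sets. Quantile normalisation left 8 probe sets, all 8 at least 2-fold, and 4 genes. Without the filter on dim probe sets 5 probe sets passed, all 5 at least 2-fold, and 3 genes; with a filter at the 60th percentile 10, all 10 at least 2-fold, and 7 genes, where 11 of the 17 genes were measured and no leukocyte marker was. limma without a variance trend called 0 probe sets, 0 of them 2-fold, and 0 genes (922 probe sets at an unadjusted p under 0.05). Camera with an estimated correlation, which has few residual degrees of freedom here, called 0 lists. The cause of the other changes was not tested.

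With the replicate number as a block, 710 probe sets passed, 193 of them at least 2-fold, with 433 genes and 10 lists; lysosome and autophagy genes and fibroblast markers were the lists added. The deviations of arrays with the same number from their group means correlated at 0.352 over probe sets, which hints at a pairing that the labels do not state. The block with a pseudocount of 64, chosen after the data were seen, gave 509 probe sets, 100 at least 2-fold, and 321 genes. The simulated share of false calls with the block, 12.5%, limits what its larger count can carry. That share came from fits with finite prior degrees of freedom. In the real fit they were infinite, so its share of false calls is not known. Acta2 passed with the block although its log2 fold changes were 0.32 and 3.26 in the batches.

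Leaving out 1 array gave 75 to 155 probe sets, 74 to 146 of them at least 2-fold, 48 to 97 genes and 10 to 19 lists. The probe sets were 155 without original 1, 82 without original 2, 75 without resistant 1 and 106 without resistant 2, and the lists 10, 17, 10 and 19. In these fits the lone array of a group is assumed to vary like the arrays of the other group, and the spread comes from 1 pair of arrays. Uncalled genes near 0 changed sign there: Cdkn1b ranged from -0.139 to 0.451, Egfr from -0.391 to 0.274, Erbb2 from -0.141 to 0.0755, Gsk3b from -0.00268 to 0.408, Vim from -0.231 to 0.0995 and Zfp36 from -0.0195 to 0.296. Signal over background limits dim genes: the original signals of Tagln (12 and 4.7) and the resistant signals of Vcan (26.9 and 6.7), Blnk (27.8 and 12.1) and Tmem185b (40.1 and 26) lie under the filter's signal of 49.1, and with a pseudocount of 64 their log2 fold changes moved to 2.46, -2.38, -1.80 and -1.56.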

Other observations

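Markers of cell identity were compared by their mean over the 4 arrays. Of 29 named epithelial marker genes 1 had a probe set brighter than the median of all probe sets, against 19 of 24 mesenchymal markers and 1 of 24 markers of leukocytes and endothelium. On each array the probe set of the adherens junction gene Cdh1 lay under the median of all probe sets, at 15.3 or less, and all 3 probe sets of Vim lay above it, at 9319.2 or more. Luminal mammary genes had 4 of 26 above that median and basal markers 6 of 22. Brightness also depends on the probes, so these counts place genes against the array and not against each other.

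Some genes outside the 8 lists that passed were not called over all genes tested and were called with the hybridisation batch as a term; they were chosen after their values were seen. Actg2, another smooth muscle actin gene, had a log2 fold change of 2.23 ± 0.478 (SE; 0.96 and 3.51 in the batches), and Has2, which makes hyaluronan, 1.15 ± 0.214 (SE), while Pdlim1, a cytoskeletal adaptor, stood at -3.27 ± 0.625 (SE; -4.28 and -2.27 in the batches) and Igf2r, the mannose 6-phosphate receptor, at -2.22 ± 0.436 (SE). The cholesterol exporters went apart, with Abca1 at 1.52 ± 0.693 (SE; 2.10 and 0.94 in the batches) and Abcg1 at -1.77 ± 0.381 (SE), and the purinergic receptor genes P2ry12 (-1.77) and P2ry14 (-1.47), which are neighbours, were both lower. Bcl2l11, which encodes the pro-apoptotic protein Bim, stood at 1.06 ± 0.223 (SE), with all 5 of its probe sets higher, and also passed when adjusted over its list alone.

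Genes were also ordered along the chromosomes, with fold changes taken relative to the median of all genes. On the chromosome that runs from Pex2 to Wls among its measured genes, 85.9% of 382 genes lay below that median, with a chromosome median of -0.321 (-0.265 and -0.345 in the batches). On the one from Selenop to Itga5, 84.4% of 307 genes lay above it, with a median of 0.27 (0.274 and 0.275 in the batches). The other 18 of 20 chromosomes with at least 100 measured genes had medians between -0.168 and 0.0665, and differences between the arrays of a group gave chromosome medians between -0.173 and 0.0256. Chromosome medians in the batches and between arrays of a group were not taken relative to the median of all genes. They therefore also hold any shift of a whole array. The largest single window of 25 genes, from Mfhas1 to Clcn3, had a median of -0.602, with 23 of its 25 genes below 0, on a chromosome whose median was 0.00752. In all, 20 separate windows exceeded the 95th percentile of the largest window in shuffled orders (0.298), 14 lower and 6 higher. Differences between the arrays of a group also passed that limit, with windows of up to 0.356 in the original population and 0.465 in the resistant pool. Counting overlapping windows, 10 and 60 of 7019 passed there, against 333 between the groups. Atp1b1 and Blnk lie in lower windows (medians -0.309 and -0.329), as do Vcam1 (-0.408), Cenpe (-0.324) and Phgdh (-0.359). Pdlim1, P2ry12, P2ry14 and Fosl1 also lie in lower windows, and Has2 in a higher one (0.313). The falls of Atp1b1, Blnk and Vcam1 were much larger than the medians of their windows.

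Tests of neighbouring genes and of spread between cultures were set before their results were seen, except that the SE of the latter's medians was added afterwards. The test of genes 50 places apart and the tests of fibroblasts, RNA integrity, leukocytes and array scaling were chosen only after the patterns or related values were seen. Those on fibroblasts, RNA integrity, leukocytes and array scaling replaced earlier versions that used fewer genes or also median centring.

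Neighbouring genes differed together between the populations: no window as large came up in 1000 shuffled orders. With the observed order counted this gives a share of 0.001, the smallest possible. Windows between the arrays of a group also passed the limit from shuffled orders, so the share alone does not measure a difference between populations. Tandem paralogs or shared probes are argued against by genes 10 places apart, whose Spearman correlation across genes was 0.147, against 0.182 for adjacent genes and 0.0232 at the 95th percentile of shuffled orders, though genes are not independent replicates. A regional property such as base composition, acting through differences between arrays, stays open for adjacent genes, which correlated at 0.0937 in the difference between the arrays of the resistant pool. It is argued against for genes 50 places apart, which correlated at 0.138 between the groups and at most at 0.0272 within a group. A gain or loss of whole chromosomes and segments in the resistant pool is a candidate explanation; no DNA was measured, and selection by EGCG and drift during culture both remain open.

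Mesenchymal markers were higher in the resistant pool, with a median of 0.481. Variation between cultures of a group stays open: the list differed by at most 0.159 (SE 0.184) between arrays of a group, from 1 pair of arrays per group. Fibroblasts mixed into the resistant cultures stay open: the 6 fibroblast markers measured outside the list had a median of 0.469, with 4 above 0 but Dcn at -2.15. For RNA integrity, the 3′ to 5′ ratio of Gapdh was at least 0.788 in the resistant and at most 0.772 in the original arrays, while that of Actb overlapped. The Gapdh ratios of the 4 arrays lay between 0.754 and 0.798, and chance separates 4 exchangeable arrays in 33.3% of cases. These ratios give no clear sign of a difference in RNA integrity, and with 2 arrays per group they do not exclude one. A difference between the resistant and original tumour cells themselves stays open as an untested hypothesis, and the opposite course of Vcan and Col1a2 leaves its extent open. Camera with an estimated correlation (0 lists called) has too few residual degrees of freedom here to decide it.

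NF-kappaB target genes were lower, with a median of -0.64. Scaling that acts alike on all genes moves the list and all genes together, so it cannot set their medians (-0.64 and 0.016) apart. Quantile normalisation could only have removed a shift that depends on brightness. Under it the list's median still lay -0.668 from that of all genes, which argues against such a shift. Variation between cultures stays open, since the list differed by up to 0.27 (SE 0.206) between arrays of a group, from 1 pair of arrays per group. Leukocytes lost from the cultures stay open: the 5 measured leukocyte and endothelial markers had a median of -0.171 (SD 0.246), with Lyz1, Lyz2, Csf1r and Cd68 above the filter's signal of 49.1 in both original arrays, while Ptprc, Tyrobp, Fcer1g and C1qa reached at most 23.6 there, too near the floor to decide. Lower NF-kappaB activity in the resistant cells stays open as an untested hypothesis, with no binding or protein measured, as does a lost copy of single members such as Vcam1 in a lower chromosome run. The fall of Vcam1 (-1.41) was larger than the median of that run (-0.408).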
